A study of Pinus pinaster with 14 samples.

How the data were processed

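The series holds 14 libraries of laser-microdissected tissues from maritime pine (Pinus pinaster, a Mediterranean conifer) seedlings harvested 1 month after shoot emergence. Laser microdissection cuts chosen cells out of a frozen section under a microscope. Per the labels' protocols, sections were cut from frozen, embedded pieces of seedling, RNA of sufficient integrity was amplified as cDNA with a conifer protocol (CRA+), and the cDNA was read by pyrosequencing on a GS-FLX+ instrument. Each tissue was 1 library. The labels do not say which seedlings, or how many, contributed to a library, so libraries may share seedlings and sections.

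The submitters' processing notes list FastQC, BWA and edgeR, with no versions, and the reference assembly is not given in the sources used here. The deposited table holds a normalised signal for 23493 transcripts in 14 columns, with transcript identifiers (16090 starting isotig, 7180 unigene, 199 PUT and 24 contig) and 0 text columns beside them. It was assumed before the data were examined that these would be plain CPM, counts scaled by the library total. The deposited signal turned out to be CPM of a library size multiplied by a normalisation factor: column sums ran from 584581 to 2176163, and the 14 factors multiply to 1. In every column 100% of the values were whole multiples, within 0.001, of what 1 read is worth in that library, so whole reads were recovered. Trimmed mean (TMM) factors computed from those reads with edgeR 4.0.16 differed from the factors in the deposited signal by a relative 4.14e-11 at most. What 1 read is worth in a library depends on its depth and on its factor: it was 3.76 in hypocotyl cortex (519134 reads, factor 0.513) and 0.652 in root meristem (1168436 reads, factor 1.31). How transcripts with few reads were removed before deposit is not given in the sources used here; the lowest total in the table was 4 reads, 1530 transcripts had fewer than 25 reads over all libraries, and 3346 reached 25 in no library.

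Recovered reads numbered 519134 to 1536389 per library and 12128688 in all. Shares of reads are given with 95% Wilson intervals. Intervals, and the limit of 3 reads used where a group had no reads, cover counting error only, because amplified cDNA reads are not independent molecules. Folds given as at least a value divide the arithmetic mean of the group with reads by that limit. They do not bound the fold in each library.

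Libraries were grouped from the labels as vascular tissue (5), ground tissue, meaning mesophyll or cortex (5), meristem (2), pith (1) and emerging needles (1). Vascular and ground tissue each came from 5 organs: young needles, cotyledons, hypocotyl, root and developing root. Tests used limma 3.58.1 in R 4.3.3 on log2(value + 5) with a mean trend in the prior variance, for transcripts at 10 or more in at least 3 libraries of the fit, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are therefore on the log2(value + 5) scale, which understates the change of low transcripts. Vascular against ground tissue had organ as a term, root against shoot had tissue group as a term, and meristems against the 10 vascular and ground tissue libraries had axis as a term. Young needles against cotyledons, and developing root against root, were contrasts between organs in a single fit of the 10 libraries. As no tissue was replicated, these p-values measure the spread between organs or tissues, not between seedlings. In the contrasts between organs, the vascular and ground tissue libraries of an organ served as its replicates. The spread there was what the organ and tissue group terms left over. Libraries of 1 organ may vary together and libraries may share seedlings, so the p-values may be too small. Similarity between libraries was tested by exact permutation over Spearman correlations across transcripts. A transcript was called preferential to a tissue when its value + 5 was at least 4 times that of the highest of the other 13 libraries, which is a rule of size with no test.

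Named transcripts followed a rule fixed before the data were examined: among those past the threshold with no overlap of the groups, the largest fold changes in each direction, limited to 2 that rose and 2 that fell because identifiers are not paired with gene names. For the same reason the gene lists and the cell type marker lists fixed beforehand were void, and 0 lists were tested. A transcript that holds a large share of reads was named after its values were seen.

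Alternatives fixed before the data were examined changed the pseudocount, the filter, the scaling between libraries, the prior, the libraries in the fit and the test, with edgeR's quasi-likelihood test and DESeq2 1.42.0 on the recovered reads. Others, added after the data were examined, ran edgeR for the remaining comparisons, removed the 10 most abundant transcripts of each library, used only shoot organs, or took off reads that certain library pairs appeared to share. For the last, the 5th percentile of the read ratio over transcripts with at least 200 reads in the source library, times the reads of the source, was subtracted, which removed 22.5% of the hypocotyl vascular reads, 18.3% of the hypocotyl pith reads and 7.10% of the apical meristem reads. The subtracted reads are called shared reads below, although whether they were shared is not settled. Except for meristems, the fit without the hypocotyl vascular library was listed before and again after the data were examined. For vascular against ground tissue and its interaction with root and shoot, this fit lacked the whole hypocotyl. The totals of alternatives below include the repeat. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

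The tests were run on simulated reads in which 200 transcripts were changed by known folds. With the spread estimated from these libraries, limma recovered 55.4% of 64-fold changes for vascular against ground tissue, 8.77% for root against shoot, 36.5% for meristems against differentiated tissues, and 0% for developing root against root. With a low spread it recovered 100% of 64-fold changes in each of these 4 comparisons. Each simulated library was drawn independently, without resemblance between libraries of an organ. The estimated spread also holds real differences between tissues. These shares therefore do not give the power of the tests on the real libraries.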

Results

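Expression was profiled in 14 tissues of 1-month-old maritime pine seedlings, each isolated by laser microdissection and sequenced as 1 library. There were 5 vascular libraries and 5 of ground tissue, paired within young needles, cotyledons, hypocotyl, root and developing root. A further 2 libraries came from the apical and root meristems, 1 from the hypocotyl pith and 1 from emerging needles. Recovered reads ranged from 519134 in hypocotyl cortex to 1536389 in root vascular tissue. No tissue had a replicate library, and the labels do not tie libraries to seedlings, so seedlings may be shared and every p-value below may be too small. Values are normalised read counts, and transcripts carry the identifiers of the deposited table because no gene names are paired with them.

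The number of transcripts with at least 1 read ranged from 8635 in young needle mesophyll to 18193 in the apical meristem, with a median of 13460 of the 23493 in the table. At 510000 reads drawn from each library, these tissues still had the fewest, 8016, and the most, 16157. A total of 2376 transcripts (10.1%) had reads in all 14 libraries and 986 had reads in a single library.

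Reads of the root and hypocotyl cortex were concentrated in few transcripts. In the root cortex, 9 transcripts held 50% of the reads, against 41 in the hypocotyl cortex and 1152 in emerging needles. The 10 most abundant transcripts held 51.4% of root cortex reads and 4.43% of emerging needle reads. A single transcript, unigene208496, named after its values were seen, accounted for 31.0% of root cortex reads (95% Wilson interval 30.9 to 31.1%). Its share was 14.9% in root vascular tissue (14.8 to 14.9%), 11.2% in hypocotyl cortex (11.1 to 11.3%) and 8.05% in developing root cortex (7.98 to 8.12%). It was lowest in young needle vascular tissue, at 0.341% (0.329 to 0.353%), and in emerging needles, at 0.343% (0.331 to 0.356%). In young needle mesophyll, cotyledon mesophyll and cotyledon vascular tissue another transcript, isotig01574, ranked first, with 2.56%, 2.89% and 3.40% of reads, and it had 10 reads in the root meristem.

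**Figure D1:**
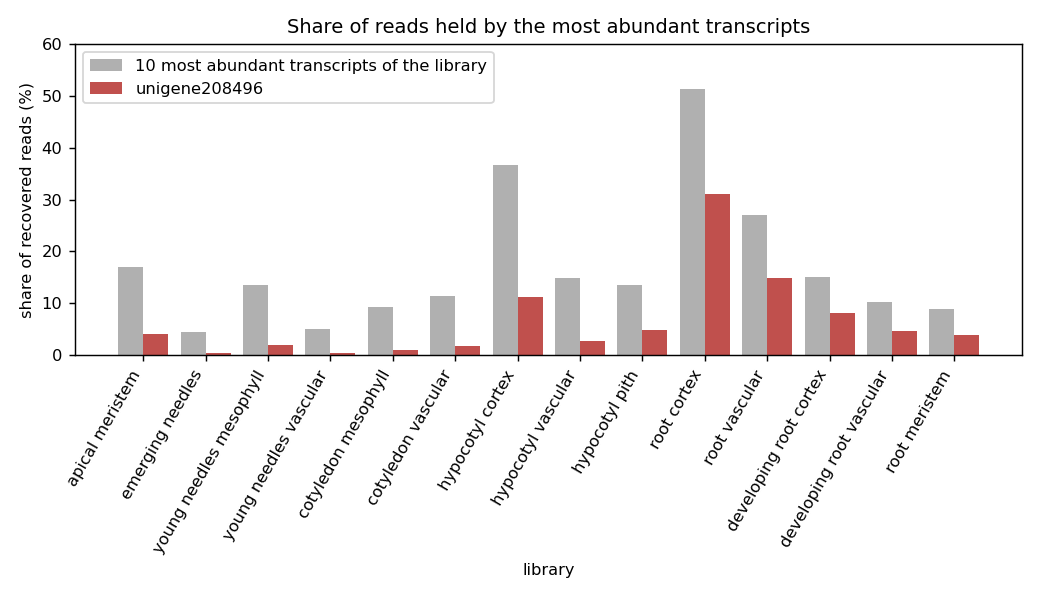
Share of recovered reads (%, vertical axis) in each of the 14 libraries (horizontal axis) held by the 10 most abundant transcripts of that library (grey bars) and by unigene208496 (red bars). Root cortex stands highest in both, at 51.4% and 31.0%.

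Whole-profile similarity was compared over 14053 transcripts. Among the 91 pairs of libraries, developing root cortex and developing root vascular tissue were the most alike (Spearman correlation across transcripts 0.766), followed by each of them with the root meristem (0.756 and 0.749). Young needle vascular tissue correlated at 0.735 with hypocotyl vascular tissue, and cotyledon mesophyll at 0.651 with hypocotyl pith. In both of these last pairs every transcript with at least 200 reads in the first library also had reads in the second. Once a share of the first library's reads was subtracted from the second, the correlations were 0.444 and 0.363. Taking a scaled copy of a library off another can lower their correlation by itself, so the fall does not show that reads were shared. Emerging needles correlated most with the root meristem (0.562) and less with young needle vascular tissue (0.357) or mesophyll (0.201). Hypocotyl cortex and root meristem were the least alike (0.0784). Transcripts are not independent replicates, so these values describe the libraries.

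**Figure D2:**
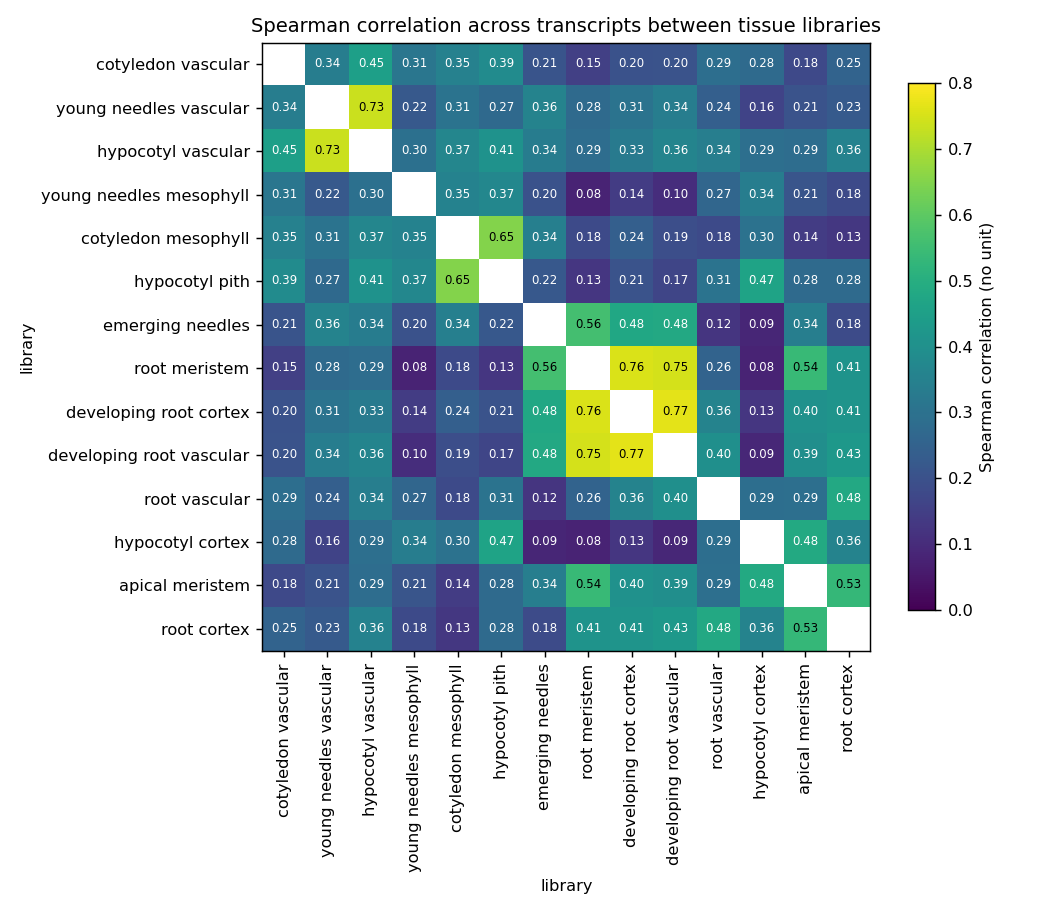
Spearman correlation across transcripts (colour scale, no unit) for each pair of the 14 libraries (both axes), ordered by hierarchical clustering. The developing root libraries and the root meristem form a block at 0.749 to 0.766.

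**Figure D3:**
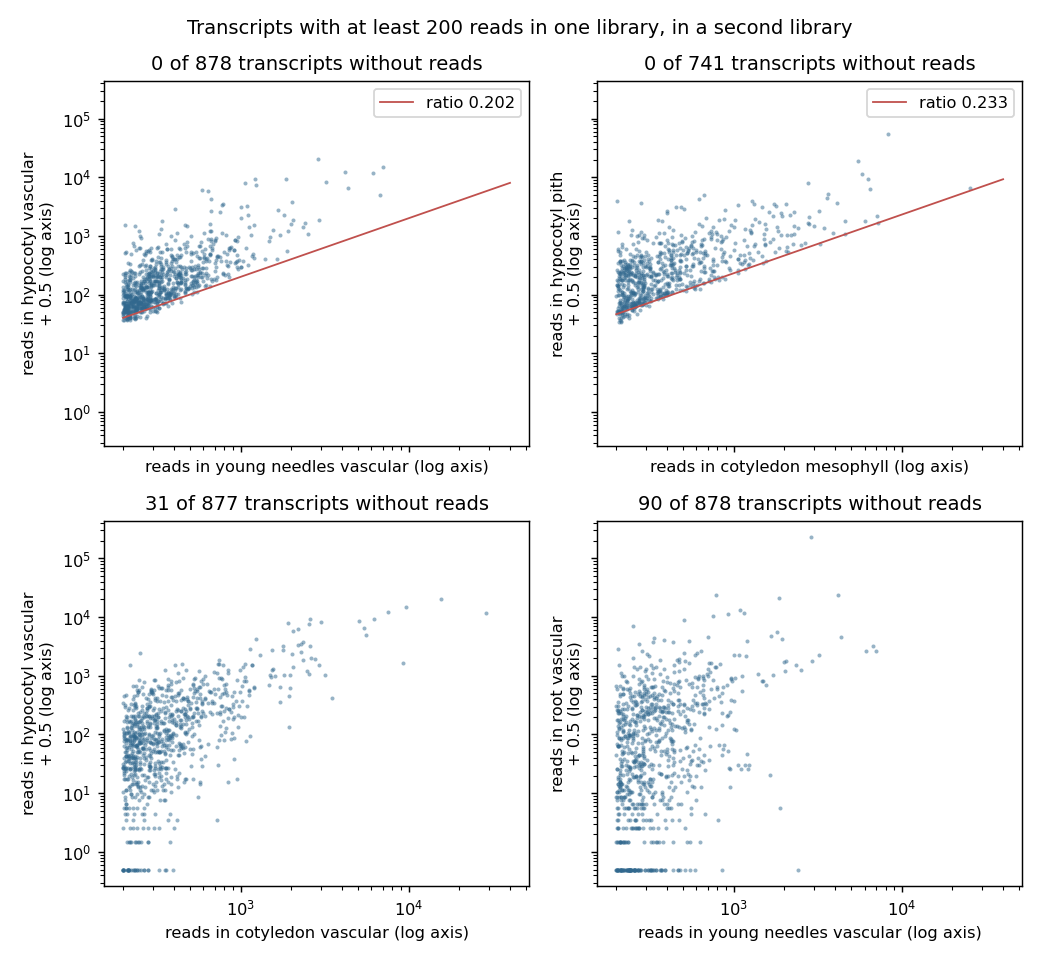
Reads of transcripts with at least 200 reads in a first library (horizontal axis, log scale) against their reads + 0.5 in a second library (vertical axis, log scale). Each point is 1 transcript, and the red line is the 5th percentile of the read ratio; 0 of 878 young needle vascular transcripts lacked reads in hypocotyl vascular tissue and 0 of 741 cotyledon mesophyll transcripts in pith, against 31 of 877 cotyledon vascular transcripts in hypocotyl vascular tissue and 90 of 878 young needle vascular transcripts in root vascular tissue.

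The 5 organs with both tissue groups showed whether a vascular library resembled the ground tissue of its own organ. Vascular and ground tissue of the same organ correlated at a mean of 0.411, against 0.234 for those of different organs, a difference of 0.177 (exact permutation test over the 120 pairings, two-sided p = 0.025). The same-organ pairs ran from 0.165 in young needles and 0.304 in the hypocotyl to 0.340 in cotyledons, 0.473 in root and 0.775 in developing root. The difference rested on the developing root: without it, it was 0.0768 (exact permutation test over 24 pairings, p = 0.25). It was 0.184 without the root and 0.229 without the hypocotyl, each with p = 0.0833 in an exact permutation test over 24 pairings. Of 597 developing root vascular transcripts with at least 200 reads, 5 lacked reads in developing root cortex. In the reverse direction 4 of 433 did. Reads carried between these libraries, or into both from the root meristem, were not subtracted. Such reads and likeness within the organ cannot be told apart there. Vascular libraries with each other and ground tissue libraries with each other correlated at a mean of 0.287, against 0.270 between the groups, a difference of 0.0178 (exact permutation test over all splits into 5 and 5, two-sided p = 0.722). The mean between the groups includes the same-organ pairs. Against vascular and ground tissue of different organs, at 0.234, the difference was 0.0532, with an exact one-sided p of 0.125 over the 16 ways to exchange the tissue groups within organs, which cannot give a p under 0.0625. It was 0.0360 after subtraction of the shared reads and, with 1 organ left out, ran from 0.0145 without the hypocotyl and 0.0268 without young needles to 0.0696 without cotyledons, 0.0766 without developing root and 0.0966 without root. With Pearson correlations it was 0.0579, with an exact one-sided p of 0.0625.

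Root and shoot libraries differed in many transcripts. Of 11163 tested, 195 were higher and 186 lower in the 4 root and developing root libraries than in the 6 needle, cotyledon and hypocotyl libraries (limma, Benjamini-Hochberg adjusted p under 0.05). Their median absolute log2 fold change was 3.70 and the smallest 2.20. The groups did not overlap for 271 of the 381, nor for 6.18% of all transcripts tested, where a random order of independent libraries would give 0.952%. Libraries of the same organ may vary together, which would raise that share, so 6.18% is not shown to exceed chance. unigene202127 averaged 3377 ± 3717 (SD, n = 4) in the root libraries, from 53.3 in root cortex to 7575 in developing root cortex, and had no reads in the 6 shoot libraries compared. Its mean in root was at least 765-fold higher, with 3 reads per shoot library as the limit. Without developing root cortex that mean was at least 448-fold higher. The log2 fold change was 7.68 ± 1.06 SE (limma adjusted p = 6.94e-06). On the log2 scale its SD was 3.30 over the 4 root libraries and 0 over the 6 shoot libraries. The fit pooled both sides, so this SE and p do not measure the spread among root libraries alone. unigene202127 stood at 1183 in the root meristem, 22.1 in the pith and 5.32 in the apical meristem. unigene17517 averaged 1930 ± 2334 (SD, n = 4) in root and had no reads in those 6 shoot libraries. Its mean in root was at least 437-fold higher, or at least 189-fold without developing root vascular tissue. The log2 fold change was 6.74 ± 1.08 SE (limma adjusted p = 6.5e-05), with a log2 SD of 3.74 in root and 0 in shoot. For both transcripts these limits hold for the mean and not for each root library. unigene17517 had 1 read in the apical meristem. With no filter both calls were lost (limma adjusted p = 0.0533 for unigene202127 and 0.109 for unigene17517). The root cortex value of unigene17517, 8.88, rested on 3 reads.

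In the opposite direction, unigene17662 averaged 2018 ± 1598 (SD, n = 6) in shoot libraries, highest in young needle mesophyll at 4672, and had no reads in the 4 root libraries, at least 386-fold lower (log2 fold change -8.14 ± 0.93 SE, limma adjusted p = 3.04e-07). unigene127440 averaged 1689 ± 1633 (SD, n = 6) in shoot and was at least 323-fold lower in root (-7.72 ± 0.92 SE, limma adjusted p = 4.43e-07). Neither had a read in the root meristem, and both had reads in the apical meristem (13.3 and 171) and emerging needles (103 and 397). The count of 381 fell to 195 without the hypocotyl vascular library, 198 without developing root vascular tissue, 212 without developing root cortex and 243 without cotyledon mesophyll. It was 156 with organ means in place of libraries, 121 with 25 added before the logarithm, 79 with no filter and 1172 with DESeq2 (443 higher and 729 lower), and quantile normalisation gave 170 higher and 238 lower.

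**Figure D4:**
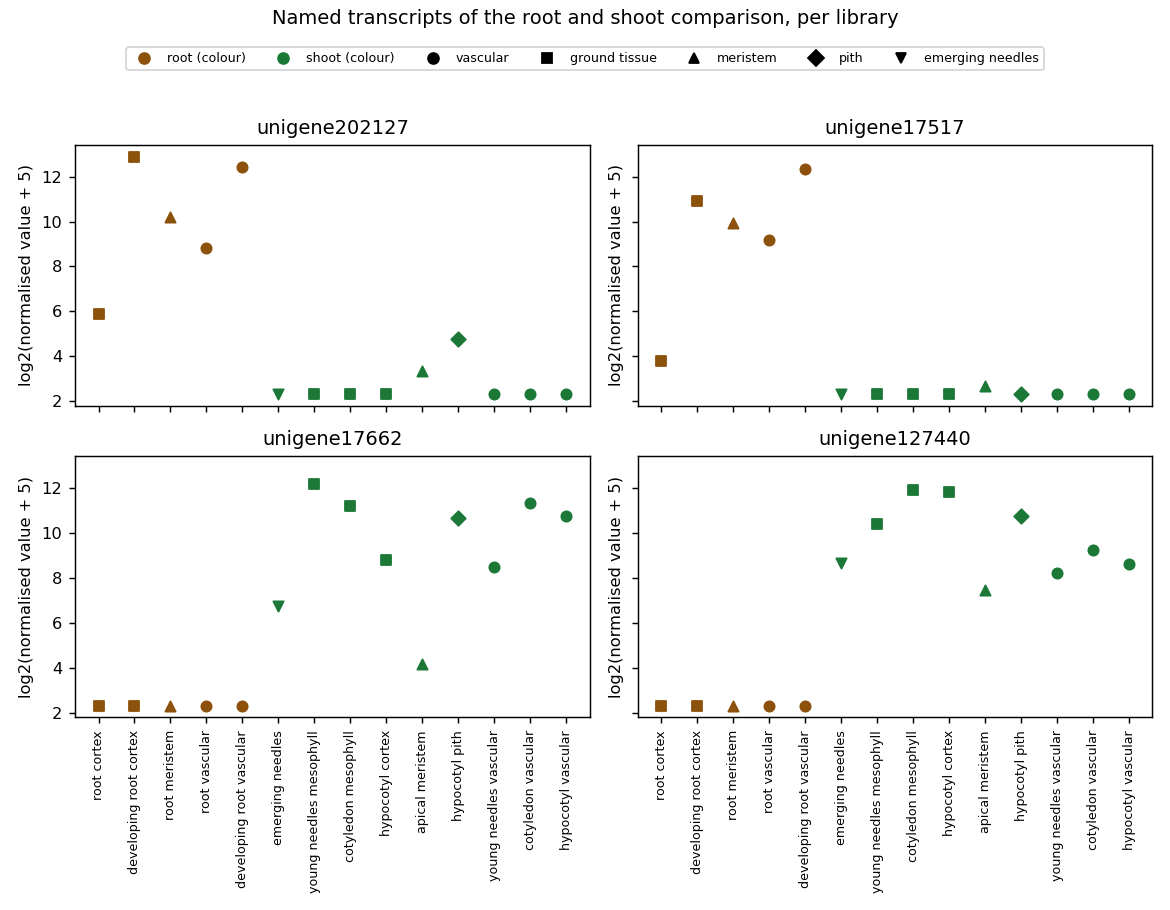
Values of the named root and shoot transcripts in each of the 14 libraries (horizontal axis), as log2(normalised value + 5) (vertical axis). Each point is 1 library, brown for root and green for shoot, with the marker giving the tissue group; unigene17662 and unigene127440 had no reads in any of the 5 brown libraries.

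Vascular against ground tissue, compared within the 5 organs, gave no transcript past the threshold among 11163 (limma, lowest adjusted p = 0.0886). At an unadjusted p under 0.05 there were 1164 transcripts, where 558 would be given by chance. There were 524 without the hypocotyl, where chance gives 452, and 706 without young needles, where it gives 489. Without the developing root there were 1061 (468 by chance), without the cotyledons 1062 (486) and without the root 1227 (478). After subtraction of the shared reads there were 939, where chance gives 536. On the recovered reads edgeR's quasi-likelihood test called 22 (15 higher and 7 lower in vascular tissue), with 670 at an unadjusted p under 0.05. DESeq2 called 243 (153 higher and 90 lower), with 1335 at an unadjusted p under 0.05. For limma without the organ term the unadjusted count was 786. A total of 72 transcripts differed by 2-fold or more in the same direction in all 5 organs, 56 higher and 16 lower in vascular tissue. Other ways to exchange the tissue groups within organs gave up to 44. In the 4 organs without the hypocotyl the real grouping gave 101 and the highest other 96. The count of 0 became 61 without the root, 38 without the developing root and 1 without the cotyledons. It became 92 in the 3 shoot organs alone (49 higher and 43 lower in vascular tissue) and 17 after quantile normalisation, and the libraries may share seedlings.

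Whether the vascular effect differed between root and shoot organs was tested as an interaction. No transcript passed the threshold (limma, lowest adjusted p = 0.377), with 755 at an unadjusted p under 0.05, where chance gives 558. With edgeR 1 was called and 334 were at an unadjusted p under 0.05, fewer than chance gives. The 755 became 113 without the root, 445 without the hypocotyl, 485 without young needles and 1267 without the cotyledons, where limma called 1.

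The 2 meristem libraries were compared with the 10 vascular and ground tissue libraries. Of 12673 transcripts none passed (limma, lowest adjusted p = 0.0884), 1083 were at an unadjusted p under 0.05, and edgeR called 0. The 1083 rested on the apical meristem: without it there were 151, where chance gives 594, with the lone root meristem library assumed to vary like the other tissues. The apical and root meristems correlated with each other at 0.539. With 25 added before the logarithm 54 transcripts were higher in meristems, with no filter 156 were higher and 2 lower, and 5 were higher without the root cortex and 3 without the root meristem.

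Between developing root and root, all 23 transcripts past the threshold among 11163 were lower in the developing root (limma), by a median of 7.39 on the log2 scale, and the smallest change was 3.83. Quantile normalisation gave 33 lower and 6 higher, and a filter at 25 gave 35 lower and 1 higher. unigene29570 averaged 11642 ± 7015 (SD, n = 2) in root, 6681 in cortex and 16602 in vascular tissue, and had no reads in developing root, at least 2989-fold lower, or 1715-fold without root vascular tissue (log2 fold change -11.04 ± 1.72 SE, limma adjusted p = 0.0032). The call was lost without root cortex (limma adjusted p = 0.165), root vascular tissue (0.146) or developing root vascular tissue (0.132), and with no filter (0.279). The transcript also had no reads in the root meristem and stood at 2800 in cotyledon vascular tissue. isotig24267 averaged 8535 ± 5095 (SD, n = 2) in root and 4.16 ± 2.95 (SD, n = 2) in developing root, where it had 6 reads (-9.76 ± 1.51 SE, limma adjusted p = 0.0032). This call was lost without root cortex (limma adjusted p = 0.114), root vascular tissue (0.269) or developing root cortex (0.144), and with no filter (0.207). The transcript reached 2992 in hypocotyl cortex and 2388 in pith. The count fell to 0 without root vascular tissue, 2 without root cortex, 7 without developing root cortex, 8 without developing root vascular tissue, and 14 without young needle mesophyll or young needle vascular tissue. It was 0 with no filter and 38 with edgeR, of which 15 were among the 23. The libraries may share seedlings, and the vascular and cortex libraries of each organ served as its replicates.

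Young needles and cotyledons, the 2 kinds of leaf, did not differ in any of 11163 transcripts at the threshold (limma, lowest adjusted p = 0.324). At an unadjusted p under 0.05 there were 837 (1355 without young needle vascular tissue), and edgeR called 0 with 1159 at an unadjusted p under 0.05. The median standard error of this contrast of 2 libraries against 2 was 1.33 on the log2 scale.

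Preferential transcripts, at least 4 times above the highest of the other 13 libraries, numbered 5330. Hypocotyl cortex had 1192, root vascular tissue 1153, young needle mesophyll 835 and cotyledon vascular tissue 535. The apical meristem had 380, hypocotyl pith 348, root cortex 250, developing root cortex 191, emerging needles 175, hypocotyl vascular tissue 129 and developing root vascular tissue 47. The smallest numbers were in cotyledon mesophyll (45), young needle vascular tissue (26) and the root meristem (24). After subtraction of the reads that library pairs appeared to share, young needle vascular tissue had 494 and cotyledon mesophyll 369. The rule asks for a value of 15 against libraries at 0, which is 4 reads in hypocotyl cortex and 24 in the root meristem. isotig57271 had 3419 reads in root vascular tissue (4843) and none in the other 13 libraries. unigene13448 stood at 3873 in root vascular tissue, with its next highest value, 3.12, in developing root cortex.

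Among the 3 hypocotyl tissues, 2167 transcripts were at least 4 times higher in cortex than in both others, 1523 in vascular tissue and 1339 in pith. After subtraction of the shared reads these were 2501, 987 and 1265. The order depended on the rule: with 1 added in place of 5 they were 3028, 3063 and 2909, and at a ratio of 2 they were 3524, 3818 and 3841. No test was made, as each tissue was a single library.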

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

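All tests weighed in this part were chosen after the result they bear on had been seen, and library values were screened for samples far from the others of their group in 44 sets of libraries. The sets were the 5 vascular, the 5 ground tissue, the 4 root and developing root and the 6 needle, cotyledon and hypocotyl libraries of the comparisons, without meristems, pith and emerging needles. Chance would mark about 1 in 20 independent sets of normal values, and 9 values were marked. That rate does not carry over here, because the sets overlap and some held transcripts named for their large differences between libraries. Root vascular tissue had 1536389 reads, against 684928 to 850625 in the other vascular libraries and 531440 to 684928 in the other 3 of the 4 root and developing root libraries; the root meristem, outside that set, had 1168436. Its most abundant transcript held 14.9% of reads, against 0.829 to 4.56% in the other vascular libraries. In hypocotyl cortex the most abundant transcript held 11.2% and the 10 most abundant 36.7%, against 0.829 to 3.40% and 4.99 to 14.8% in the other 5 of the 6 shoot libraries compared. On the log2(value + 5) scale isotig24267 stood at 12.27 in root vascular tissue, far above the other vascular libraries, which reached 5.04, and at 11.55 in hypocotyl cortex, where the other 5 of the 6 shoot libraries compared reached 5.38; outside that set its value was 2501 in the apical meristem and 2388 in pith, against 2992 in hypocotyl cortex. unigene17517 stood at 10.91 in developing root cortex, with the other ground tissues at 3.80 or less, and unigene29570 at 12.71 in root cortex, with the others at 2.55 or less.

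A feature outside those screens concerned pairs of libraries. In 4 of 182 ordered pairs, no transcript with at least 200 reads in the first library was without reads in the second: young needle vascular tissue in hypocotyl vascular tissue (878 transcripts), cotyledon mesophyll in hypocotyl pith (741), hypocotyl cortex in the apical meristem (237) and root cortex in the apical meristem (203). In the other 178 pairs 0.0947 to 37.4% of such transcripts were without reads, with a median of 10.3%. For the 204 transcripts preferential to young needle vascular tissue when the second library is left out of account, reads in hypocotyl vascular tissue followed those in the needles at a median ratio of 0.216, with a spread beyond counting error of 0.128. For the 104 of cotyledon mesophyll the ratio in hypocotyl pith was 0.257 and the spread 0.274. Of the 178 pairs in which some abundant transcript was without reads, 74 had an estimate, and their lowest spread was 0.904. In the reverse direction, 2 of 506 abundant hypocotyl vascular transcripts (0.395%) had no reads in young needle vascular tissue, with a spread of 1.18 over 19 preferential transcripts, and 52 of 895 abundant pith transcripts (5.81%) had none in cotyledon mesophyll. The share of 0.0947% was that of root meristem transcripts in developing root cortex and in developing root vascular tissue, each lacking 1 of 1056. By the 5th percentile of the ratio these would amount to 13.9% of the reads of each. Spreads of 1.79 and 0.924 leave carried-over reads and shared expression unable to be separated. Nothing was subtracted for these pairs, so their correlations include any such reads.

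Expression shared by vascular tissues is argued against as the whole cause. Among the 9 other ordered vascular pairs with an estimate the lowest spread was 1.18, for the same 2 libraries in reverse. The next lowest was 1.21, for developing root vascular tissue in hypocotyl vascular tissue. Neither cotyledon mesophyll nor hypocotyl pith is vascular, so this explanation does not reach that pair. Expression shared by mesophyll and pith was not tested. Greater depth is argued against too, since the deepest library, root vascular tissue, lacked 10.3% of the abundant young needle vascular transcripts. The values are consistent with reads or cDNA of one library having been counted in the other, amounting by the 5th percentile of the ratio to 23.0% of hypocotyl vascular and 18.8% of pith reads. Whether this arose in the tissue, in amplification, in sequencing or in read handling stays open, as does a mixture in the seedling itself. For the apical meristem the spreads of 2.26 with hypocotyl cortex and 0.864 with root cortex leave carried-over reads and the meristem's own expression unable to be separated, because a transcript that the meristem also expresses widens the spread.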

How the results depend on the processing

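Alternatives that subtracted shared reads, left out hypocotyl vascular tissue together with the apical meristem, removed abundant transcripts, used shoot organs only, left out an organ or the same-organ pairs in the similarity comparisons, or ran edgeR for other comparisons than root against shoot, vascular against ground tissue and meristems were chosen after seeing the data; the others were chosen before the data were examined. For root against shoot, 15 of 25 alternatives gave 258 to 408 transcripts (main value 381). The others gave 121 with 25 added before the logarithm, 79 with no filter, 1172 with DESeq2, 156 with organ means, 175 without the hypocotyl and 195 without the hypocotyl vascular library; leaving out 1 library gave 195 to 383. Quantile normalisation moved the split from 195 higher and 186 lower to 170 and 238, and the median log2 fold change of all transcripts from 0.25 to 0.09. The 4 named transcripts kept their direction wherever they were tested and passed the threshold except unigene202127 (adjusted p = 0.0533) and unigene17517 (adjusted p = 0.109) with no filter; unigene17517 was tested in 7 of the 10 fits with a library left out, where its log2 fold change ran from 6.58 to 8.5. For vascular against ground tissue, 10 of 19 alternatives gave 0; the others gave 1 with a filter at 25, 17 with quantile normalisation, 22 with edgeR, 243 with DESeq2, 92 with shoot organs only and 106 with those after subtraction of shared reads, and leaving out 1 organ gave 0 to 61. The interaction gave 3 with quantile normalisation, 1 with edgeR and 0 to 1 with an organ left out. Meristems gave 54 with 25 added, 158 with no filter and 0 to 5 with a library left out. Young needles against cotyledons gave 0 in all 20. Developing root against root gave 18 to 29 in 8 of 20 alternatives (main value 23), 9 with 25 added, 0 with no filter, 36 with a filter at 25, 39 with quantile normalisation (6 higher), 14 with no trend in the prior, 38 with edgeR, and 0 to 29 with a library left out (0 without root vascular tissue); adjusted p ran from 2.71e-08 to 0.279 for unigene29570 and from 0.000248 to 0.269 for isotig24267. Same-organ similarity was 0.229 without the hypocotyl (exact permutation p = 0.0833, 24 pairings), which has fewer libraries, 0.101 to 0.193 with another correlation, filter or subtraction, and 0.0768 (without developing root, exact permutation p = 0.25) to 0.241 (without young needles) with another organ left out. Same-class similarity reversed to -0.0025 after subtraction (exact permutation p = 0.96) and -0.0428 without the hypocotyl (p = 0.514), and ran from -0.0335 (without young needles) to 0.0574 with another organ left out; these values include the same-organ pairs in the mean between groups, and over pairs of different organs the difference was 0.0532 and did not reverse after subtraction (0.0360) or with any 1 organ left out (0.0145 to 0.0966). Preferential transcripts numbered 2473 with 25 added, 11900 at a ratio of 2 and 2571 at 8, and those within the hypocotyl 9000 with 1 added, 1528 with 25, 11183 at a ratio of 2 and 2289 at 8. Median transcripts detected were 7861 at a value of 10 and 5234 at 25. Except where fewer libraries or another rule of size show it, the cause was not tested. The 25, 19 and 20 alternatives each include 1 repeated fit, as do the 10 of 19 and 8 of 20. The alternative for the void gene lists was not run. The limit of 3 reads reflects scaling as well as depth. It was 11.3 in hypocotyl cortex (519134 reads), 4.68 in developing root cortex (531440) and 1.96 in root meristem.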

Other observations

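The tests in this part were chosen after the values had been seen. Emerging needles correlated at 0.483 with developing root vascular tissue and 0.478 with developing root cortex, above their 0.341 with the apical meristem and 0.208 with cotyledon vascular tissue. Libraries whose labels say emerging, developing or meristem are called growing below. They were emerging needles, developing root cortex, developing root vascular tissue and both meristems. Young needles were counted among the other 9 libraries. With the root meristem, young needle mesophyll correlated at 0.0808 and young needle vascular tissue at 0.276. The growing libraries had a mean correlation with each other of 0.547, against 0.247 with the other 9. The apical meristem was an exception: it correlated more with root cortex (0.534) and hypocotyl cortex (0.485) than with developing root cortex (0.405), developing root vascular tissue (0.395) or emerging needles, also after subtraction of the shared reads (0.482 and 0.410 against 0.400, 0.391 and 0.340).

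A hypothesis is that growing organs may share part of their expression across root and shoot. The mean of 0.547 includes 3 pairs within the root; the 6 pairs of a growing root with a growing shoot library averaged 0.477, against 0.231 over the other 39 pairs of a root with a shoot library, of which the highest was 0.534 (apical meristem with root cortex). Of the 360 choices of 3 root and 2 shoot libraries, 1, the real one, gave a difference of 0.30 or more and the highest other gave 0.249, but the tissues were put together after the correlations had been seen, so this count says nothing about chance. Reads of emerging needles carried into the root meristem are argued against. Of the transcripts with at least 100 reads in emerging needles, and preferential to them with the root meristem left out of account, 49.0% had no reads there. In the reverse direction, 17 of 1056 abundant root meristem transcripts (1.61%) lacked reads in emerging needles, as did 3 of 18 preferential ones (16.7%). Root meristem reads carried into emerging needles therefore stay open. The same holds for the apical meristem, where 14 of 1056 (1.33%) lacked reads, and for each developing root library, where 1 of 1056 did. Nothing was subtracted for these pairs, so the correlations behind this hypothesis include any such reads. Unequal depth is argued against by a correlation of 0.556 with the root meristem at equal depth. The concentration of reads in few transcripts, lower in these libraries than in root and hypocotyl cortex, and a shared handling of samples stay open.

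The count of transcripts between root and shoot was set against other groupings of the 10 libraries. Of 100 splits into 4 and 6, 1, the real one, called as many as 381, and the highest other called 79. The 100 held every split of whole organs and others drawn at random. They bear on chance only for independent libraries, so chance is not excluded by them. Libraries of the same organ may resemble each other, as those of the developing root did, and of the 10 ways to choose 2 organs from 5, 1, the real one, called as many, with 23 in the highest other; 10 splits cannot give a share under 0.05. Reads of young needle vascular tissue in the hypocotyl vascular library are argued against as the whole cause. After subtraction of the shared reads 374 transcripts were called. Among the 10 libraries of the fit, that subtraction altered only hypocotyl vascular tissue. Reads shared among the root meristem and the developing root libraries were not subtracted and stay open. A few dominant transcripts are argued against as the whole cause too. After removal of the 10 most abundant transcripts of each library 369 were called. Seedlings common to several libraries remain open.

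For vascular against ground tissue, the real split called 0, so each of the 100 splits gave as many by construction and their number says nothing about chance. The highest other split called 98. It placed young needle and cotyledon mesophyll and hypocotyl cortex with both root libraries, and so compared the tissue groups in the 3 shoot organs only, which points to a structure of the samples. Of the 16 sign flips of the organ pairs, 1, the real one, gave 72 transcripts apart by 2-fold or more in the same direction in all 5 organs, and the highest other gave 44. The flips are too few for a share under 0.05. After subtraction of the shared reads the numbers were 61 and 35, and in the 4 organs without the hypocotyl they were 101 and 96.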
